A study of Homo sapiens with 24 samples.

How the data were processed

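Human RUES2 embryonic stem cells, an established line, were differentiated for 5 days into 3 populations, per the labels. C-EC are endothelial cells of cardiogenic mesoderm, made with 100 ng/mL activin A and then 5 ng/mL BMP4. H-EC are hemogenic endothelial cells, made with 50 ng/mL activin A and then 40 ng/mL BMP4. CPC are cardiac progenitor cells, made with 100 ng/mL activin A and a BMP4 dose that is not given in the sources used here. RNA-seq, H3K4me3 and H3K27me3 chromatin immunoprecipitation and chromatin input were each labelled with 2 biological replicates per population, which makes 24 samples in 12 groups. RNA came from bulk cultures, per the labels, and chromatin was fixed with formaldehyde.

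Per the submitters' processing notes, the tools were Bowtie2, TopHat 1.3.3, MACS 1.4.2 and DESeq on hg19; the role of each for the RNA values is not given in the sources used here. The authors deposited 1 expression table in TPM, 1 column per library, with 57773 genes. The column sums ran from 871076 to 1018176 TPM and no value was exactly zero. Whether a further rescaling or estimation step was applied is not given in the sources used here. The read depth of the RNA libraries is unknown, since TPM holds no counts, and no counting interval was computed. The authors deposited 1 MACS peak list per population and mark, with peak tags as counts, a score (10 times the negative log10 of the p-value), fold enrichment as a ratio and false discovery rate as a percent, per the file headers. Both replicates point to the same list, per the labels, so the spread between chromatin replicates is unknown and no test between populations was made on the marks. Per the file headers, the immunoprecipitated tags per list ran from 14945730 in CPC H3K27me3 to 34433529 in C-EC H3K27me3. The input tags were 21683346 in C-EC, 20362949 in H-EC and 5324749 in CPC.

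Genes with at least 1 TPM in at least 2 of the 6 libraries were tested, which left 28997 genes (50.2%). The values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model over all 3 groups, empirical Bayes with a variance trend, 3 residual degrees of freedom, two-sided). P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Gene lists were tested with camera in limma, at a preset correlation between genes of 0.01, adjusted over the 23 lists within each comparison (69 tests in all). Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation also rests on the 3 residual degrees of freedom. A missing call in that setting alone therefore cannot tell correlated genes from this lack of degrees of freedom. For the hypoxia and glycolysis list the estimated correlation was −0.003, below the preset. Its call in H-EC minus CPC still ended (camera adjusted p = 0.019 with the preset and 0.293 with the estimate). A higher correlation was not the reason there. Changes are given on the log2(TPM + 1) scale with the standard error (SE) of limma, and levels as mean TPM ± SD of 2 libraries.

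Peaks were placed on GRCh37 with GENCODE genes, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. A promoter was the window of 2000 bp on each side of the canonical transcription start site of 19391 protein-coding genes, and carried a mark where a peak overlapped it by at least 1 bp. Shares of overlapped peaks have Wilson 95% intervals, which cover counting error only. The genes whose promoter carried a mark in 1 population and not in another formed 12 sets, tested with camera on the expression difference between the same populations.

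The gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. The rule took HOPX, which the series title names, the 6 genes with the largest change each way in each comparison, and up to 4 members of each list with the largest change. The top genes had to pass the threshold, reach a mean of 10 TPM in the higher group and have no overlap between the libraries of the 2 groups. For the marks it took named regulators and the genes named for expression; PECAM1 was not analysed here.

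The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, quantile scaling, TMM scaling (a reimplementation of its formula on TPM), no variance trend, a fit of only the groups compared, a 2-fold minimum, a replicate block, each library left out, a MACS score of at least 100, peak lists of equal length, an overlap of 50% of the peak and promoter windows of 1000 and 5000 bp. A fit of protein-coding genes alone, joining of peaks within 1000 bp and promoters at any annotated start site were chosen after seeing the data. The test for single genes, camera and the peak overlap were also tested on simulated data. The replicate-level chromatin signal was not used here, since the files hold 1 list per population and mark.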

Results

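Expression and 2 histone marks were measured at day 5 in 3 populations derived from RUES2 human embryonic stem cells. These were endothelial cells of cardiogenic mesoderm (C-EC), hemogenic endothelial cells (H-EC) and cardiac progenitor cells (CPC). H3K4me3 marks active or poised promoters, and H3K27me3 marks promoters under Polycomb repression. Each population had 2 RNA libraries. The RNA depth is unknown because only TPM are held. Replicates correlated across genes at r = 0.986 in C-EC, 0.982 in H-EC and 0.985 in CPC on the log2 scale, where genes are not independent replicates. The highest correlation between libraries of different populations was 0.95 for C-EC and H-EC, 0.899 for C-EC and CPC, and 0.912 for H-EC and CPC.

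Of all tested genes, 40.5% were called in H-EC minus C-EC, 57.8% in C-EC minus CPC and 52.6% in H-EC minus CPC. Counts of called list members are to be read beside these shares. Of the genes called, 57.3% in H-EC minus C-EC, 52% in C-EC minus CPC and 52.6% in H-EC minus CPC were not protein-coding, and many of these are short. Of 3043 microRNA genes in the table, 2977 (97.8%) passed the filter on low values, and so did 1854 of 1912 snRNA genes (97%) and 1377 of 1457 snoRNA genes (94.5%). Their library medians lay at 9.42 to 11.13 TPM for microRNA genes, against 3.28 to 3.61 TPM for protein-coding genes. Processed pseudogenes of up to 200 bp had a median of 9.60 TPM, against 0.045 TPM from 200 to 500 bp and 0.23 TPM above 500 bp. The cause was not tested. The overall counts of genes in each comparison below are therefore followed by those of a fit of the 13196 tested protein-coding genes alone, an alternative chosen after seeing the data.

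The comparison of H-EC with C-EC asks how the endothelial populations of hemogenic and cardiogenic mesoderm differ. The tested HOXB genes, which pattern the body axis, were higher in H-EC except HOXB1. HOXB8 stood at 23.03 ± 0.305 TPM in H-EC and 1.82 ± 0.356 in C-EC (SD, n = 2 each, as for all levels below). Arterial genes were higher too, among them GJA4, a gap junction protein, with 111 ± 0.93 TPM in H-EC and 28.7 ± 7.71 in C-EC. ETV2, a transcription factor that specifies endothelium and blood, was lower in H-EC, at 1.34 ± 0.081 TPM against 8.57 ± 0.095. The genes with the largest increase on the log2 scale were LUM and COL3A1: COL3A1, a fibrillar collagen, stood at 489 ± 200 TPM in H-EC and 9.14 ± 0.329 in C-EC, and LUM, a proteoglycan, at 93.5 ± 15.6 and 0.877 ± 0.013. In CPC the same genes differed between replicates, with COL3A1 at 198 and 70.6 TPM and LUM at 32.9 and 11.5 TPM.

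HOPX (ENSG00000171476; chromosome 4, 57514155 to 57548043, minus strand, GRCh37), an atypical homeodomain protein named in the series title, was expressed in both endothelial populations. Its level was 59.5 ± 7.10 TPM in C-EC, 35.4 ± 6.16 in H-EC and 1.26 ± 0.305 in CPC. The difference H-EC minus C-EC was −0.74 on the log2 scale (SE 0.158, limma adjusted p = 0.0147). This call ended without C-EC replicate 1 (HOPX adjusted p = 0.078), without H-EC replicate 1 (0.061) and with no filter (0.0826), over a range of 0.00786 to 0.0826 in the 16 alternatives. Against CPC, HOPX was higher by 4.74 in C-EC (SE 0.158, limma adjusted p = 2.71e-05) and by 4.01 in H-EC (SE 0.158, limma adjusted p = 5.32e-05).

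Of the HOXA and HOXB list, 9 of 10 tested members were higher in H-EC and 1, HOXB1, did not pass. The same 9 passed adjusted over the list alone. The list held 21 measured members, and HOXA13 was the only HOXA gene tested. HOXA13, HOXB4, HOXB5, HOXB6, HOXB7 and HOXB9 reached 1 TPM in 2 libraries only through H-EC. For these a higher level in H-EC was largely set by the filter, which also limits the camera result. HOXB6 differed by 3.32 (SE 0.305), HOXB8 by 3.10 (SE 0.125) and HOXB5 by 2.61 (SE 0.149). The list was called by camera (adjusted p = 2.35e-05; adjusted p = 0.594 with an estimated correlation). Of 14 arterial genes, 10 were higher in H-EC, 1 was lower and 3 did not pass, with 10 and 1 adjusted over the list alone. GJA5 differed by 2.02 (SE 0.101), GJA4 by 1.93 (SE 0.169), and DLL4, a Notch ligand, by 1.78 (SE 0.232). Camera called the list higher (adjusted p = 0.000512; adjusted p = 0.643 with an estimated correlation).

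Of 14 proliferation genes, 11 were lower in H-EC and 1, PCNA, was higher, with 11 and 1 adjusted over the list alone. PCNA had 24.1 and 26.9 TPM in the H-EC libraries and 21.4 and 20.6 in those of C-EC. The replication genes MCM2 and MCM5 did not pass. PLK1, a mitotic kinase, had 33.6 ± 1.97 TPM in H-EC and 68.7 ± 3.57 in C-EC, and MKI67 had 10.7 ± 0.543 and 20.5 ± 2.50. Camera called this list lower (adjusted p = 0.000435; adjusted p = 0.594 with an estimated correlation). Of 15 regulators of hemogenic endothelium and blood, 9 were lower in H-EC, 1 was higher and 5 did not pass, with 10 lower and 1 higher adjusted over the list alone. CBFA2T3, a transcriptional corepressor, fell by 1.67 on the log2 scale (SE 0.116), and IKZF1, a zinc finger factor of lymphoid cells, fell by 0.71 (SE 0.093). MYB was the gene that was higher, at 4.63 and 4.02 TPM in the H-EC libraries against 2.68 and 2.27 in C-EC. RUNX1 did not pass, with 2.44 and 3.07 TPM in H-EC against 2.51 and 1.68. Camera gave this list an adjusted p = 0.0211, and an adjusted p = 0.643 with an estimated correlation. The call ended among protein-coding genes alone (adjusted p = 0.0555), over a range of 0.00542 to 0.643 in the 18 alternatives. Of 11 stress genes, 6 were lower and 5 did not pass, with 8 lower and 1 higher adjusted over the list alone. JUN had 4.88 ± 0.152 TPM in H-EC and 7.80 ± 0.304 in C-EC. Camera gave an adjusted p = 0.033, and an adjusted p = 0.643 with an estimated correlation. That call ended without C-EC replicate 2 (adjusted p = 0.0742), with a filter of 5 TPM (0.136) and among protein-coding genes alone (0.0788), over a range of 0.0166 to 0.643.

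Of 25 pan-endothelial genes, 8 were lower in H-EC, 2 were higher and 15 did not pass, with 9 and 2 adjusted over the list alone. CD34, a surface marker of endothelium and blood progenitors, had 105.5 ± 10.2 TPM in H-EC and 227 ± 9.71 in C-EC, and EGFL7 had 103 ± 1.45 and 225 ± 7.77. The CD34 call ended with no filter (adjusted p = 0.0502). This list was not called (adjusted p = 0.0652; adjusted p = 0.776 with an estimated correlation). It passed as lower with a pseudocount of 5 (0.0158), no filter (0.0252), a filter of 5 TPM (0.014) or the compared groups alone (0.0119), and without C-EC replicate 2 (0.0218), H-EC replicate 2 (0.0441), CPC replicate 1 (0.0105) or CPC replicate 2 (0.0105). Of 13 fibroblast and matrix genes, markers of another cell type, 7 were higher in H-EC, 2 were lower and 4 did not pass, with no call (camera adjusted p = 0.0775; adjusted p = 0.776 with an estimated correlation). Among protein-coding genes alone it was 0.00763, and adjusted p = 0.631 with an estimated correlation. The list also passed with no filter (0.0252) or the compared groups alone (0.0336), and without H-EC replicate 2 (0.0238), CPC replicate 1 (0.0342) or CPC replicate 2 (0.0342). COL6A3 was among those higher, with 33.4 ± 10.1 TPM in H-EC and 3.42 ± 0.661 in C-EC, while PDGFRA was lower, with 15.3 ± 0.832 and 119.7 ± 24.2. Of 13 endoderm genes, also of another cell type, 5 were higher and 2 lower, with no call (camera adjusted p = 0.101; adjusted p = 0.776 with an estimated correlation). Among protein-coding genes alone, with 12 members, it was 0.00763, and adjusted p = 0.631 with an estimated correlation. This list also passed with no filter (0.0252), a filter of 5 TPM (0.048) or the compared groups alone (0.0336), and without CPC replicate 1 (0.0342) or CPC replicate 2 (0.0337). APOA2, an apolipoprotein, had 109 ± 6.65 TPM in H-EC and 5.16 ± 0.735 in C-EC. The endocardial list was not called (9 lower, 2 higher, camera adjusted p = 0.119). Neither were the cardiac transcription factors (7 lower, 1 higher, 0.151) nor the venous and lymphatic genes (6 lower, 3 higher, 0.2). With fry, which tests another question, these lists passed as lower (adjusted p = 0.02, 0.0419 and 0.0164).

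In all, 5926 genes were higher and 5818 lower in H-EC than in C-EC, of which 845 and 550 changed at least 2-fold. Among protein-coding genes alone, 1954 were higher and 3268 lower, of which 297 and 303 changed at least 2-fold, so the share higher of all called was 37.4% in place of 50.5%. The 6 genes with the largest increase were LUM, COL3A1, AC132217.4, GS1-21A4.1, H19 and RP11-85G21.3, with LUM at 5.64 (SE 0.437, limma adjusted p = 0.000695) and H19, an imprinted RNA, at 4.42 (SE 0.26, limma adjusted p = 0.000435). The 6 with the largest decrease were the gene with identifier ENSG00000258569, HMGA1P5, SMARCE1P4, RN7SL103P, RP11-206M11.7 and CST1, of which CST1, a cystatin, fell by 3.33 on the log2 scale (SE 0.143, limma adjusted p = 0.000322). The call of HMGA1P5, which fell by 4.37 (SE 1.033, limma adjusted p = 0.0202), ended without C-EC replicate 1 (0.0695), C-EC replicate 2 (0.0938), H-EC replicate 1 (0.0756) or H-EC replicate 2 (0.0741), and with no filter (0.116). The number of genes lower was 3606 without C-EC replicate 1 and 3757 without C-EC replicate 2.

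**Figure D1:**
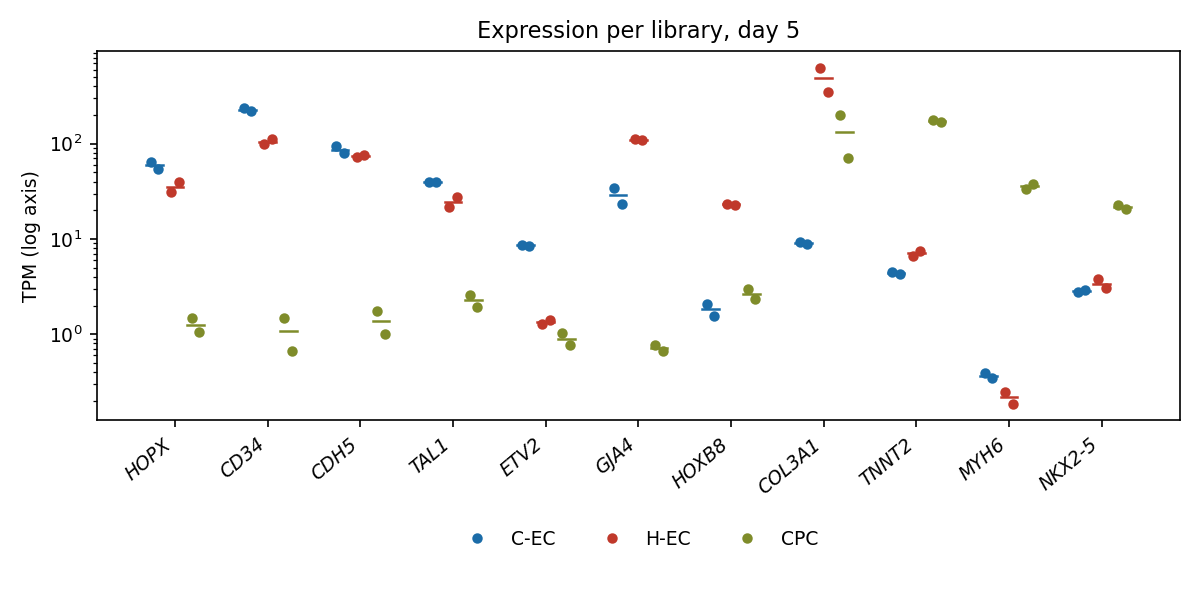
TPM on a log axis for 11 genes in each library of C-EC, H-EC and CPC at day 5; points are libraries (n = 2 each) and lines are means. HOXB8 and COL3A1 stand higher in H-EC than in C-EC, and HOPX stands at 59.5, 35.4 and 1.26 TPM in C-EC, H-EC and CPC.

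**Figure D2:**
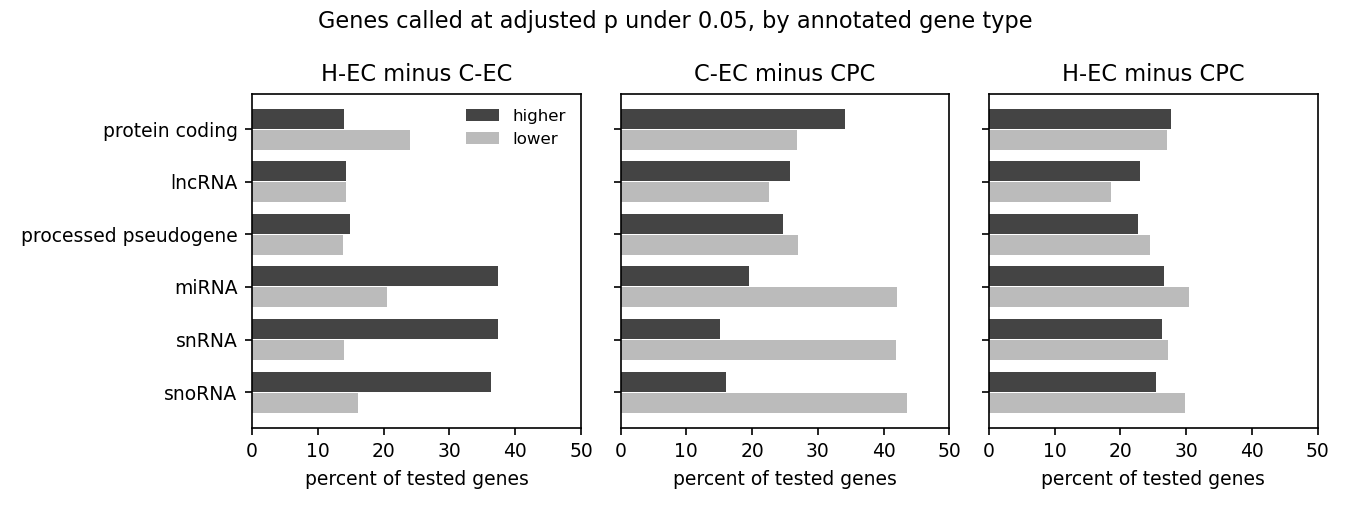
Percent of tested genes called higher (dark bars) or lower (light bars) at the 0.05 threshold in each comparison, by annotated gene type. The microRNA, snRNA and snoRNA genes and the protein-coding genes lean to opposite sides in H-EC minus C-EC and in C-EC minus CPC.

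The comparison of C-EC with CPC sets endothelium against heart muscle progenitors of the same day. Endothelial genes were far higher in C-EC: CD34 stood at 227 ± 9.71 TPM against 1.07 ± 0.566 in CPC, and SOX7, an endothelial transcription factor, at 84.2 ± 8.08 against 0.797 ± 0.273. Heart muscle genes were far higher in CPC. TNNT2, cardiac troponin T, stood at 173 ± 4.73 TPM in CPC and 4.38 ± 0.113 in C-EC. MYH6, a cardiac myosin, stood at 35.7 ± 2.93 and 0.368 ± 0.032.

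Of 25 pan-endothelial genes, 24 were higher in C-EC and 1 did not pass, with 24 adjusted over the list alone (camera adjusted p = 1.98e-14; adjusted p = 0.43 with an estimated correlation). CD34 differed by 6.81 (SE 0.185), ECSCR by 6.28 (SE 0.198) and PLVAP by 6.03 (SE 0.249). Of 15 sarcomere genes, 14 were lower in C-EC and 1 did not pass, with 14 adjusted over the list alone (camera adjusted p = 2.17e-08; adjusted p = 0.43 with an estimated correlation). TNNT2 fell by 5.01 on the log2 scale (SE 0.075) and TNNI1 fell by 4.84 (SE 0.16). Of 15 regulators of hemogenic endothelium and blood, 11 were higher and 2 lower, with 11 and 2 adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.442 with an estimated correlation). TAL1, a transcription factor of blood and endothelium, had 39.8 ± 0.224 TPM in C-EC and 2.26 ± 0.453 in CPC, and LMO2, its partner, had 59.5 ± 0.169 and 6.08 ± 0.162. Of 9 venous and lymphatic genes, 6 were higher and 3 did not pass, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00362; adjusted p = 0.43 with an estimated correlation). FLT4, a receptor for lymphatic growth factors, had 52.7 ± 6.43 TPM in C-EC and 2.02 ± 0.022 in CPC.

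Of 15 cardiac transcription factors, 9 were lower in C-EC, 2 were higher and 4 did not pass, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.442 with an estimated correlation). MYOCD, a cofactor of muscle genes, had 0.546 ± 0.059 TPM in C-EC and 18.5 ± 5.49 in CPC, and NKX2-5 had 2.84 ± 0.129 and 21.6 ± 1.49. HOPX, a member of this list, was higher. Of 11 stress genes, 8 were higher in C-EC and 3 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.43 with an estimated correlation). JUN had 7.80 ± 0.304 TPM in C-EC and 0.934 ± 0.042 in CPC. Of 13 endoderm genes, markers of another cell type, 10 were lower in C-EC and 3 did not pass, with 10 adjusted over the list alone (camera adjusted p = 0.00362; adjusted p = 0.563 with an estimated correlation). FOXA2 had 0.811 ± 0.077 TPM in C-EC and 13.5 ± 4.38 in CPC, and EPCAM had 12.5 ± 1.04 and 88.6 ± 17.1. Of 17 endocardial genes, 8 were higher and 8 lower, with a mean of 0.003, a median of −0.33 and no call (camera adjusted p = 0.78). The HOXA and HOXB list had 1 gene higher, 2 lower and 7 that did not pass, with a mean of 0.06, a median of −0.06 and no call (camera adjusted p = 0.908). The lists of arterial genes (7 higher, 5 lower; camera adjusted p = 0.296), proliferation genes (6 lower, 2 higher; 0.302) and fibroblast and matrix genes (4 higher, 3 lower; 0.823) were not called either.

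In all, 7933 genes were higher and 8820 lower in C-EC than in CPC, of which 1888 and 1650 changed at least 2-fold. Among protein-coding genes alone, 4664 were higher and 3694 lower, of which 1381 and 777 changed at least 2-fold, so the share higher of all called was 55.8% in place of 47.4%. The 6 genes with the largest increase were CD34, ECSCR, PLVAP, LAPTM5, SOX7 and GMFG. The 6 with the largest decrease were TNNT2, TNNI1, INSL6, MYH6, TTN-AS1 and CXCR4.

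The comparison of H-EC with CPC sets hemogenic endothelium against the same progenitors. It shares the CPC libraries with the comparison above, so the changes of the 2 comparisons are not independent. Endothelial genes were higher in H-EC, with ECSCR at 361 ± 27.7 TPM against 3.72 ± 1.31 in CPC and GJA4 at 111 ± 0.93 against 0.715 ± 0.072. Heart muscle genes were lower, with TNNT2 at 7.07 ± 0.621 TPM in H-EC and 173 ± 4.73 in CPC and NEBL at 5.11 ± 0.131 and 119 ± 28.4. Proliferation genes were lower in H-EC throughout the list, with PCNA, a DNA replication clamp, at 25.5 ± 1.98 TPM and 66.4 ± 0.739.

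Of 25 pan-endothelial genes, 22 were higher in H-EC and 3 did not pass, with 23 adjusted over the list alone (camera adjusted p = 3.5e-14; adjusted p = 0.293 with an estimated correlation). Of 15 sarcomere genes, 14 were lower and 1 was higher, with 14 and 1 adjusted over the list alone (camera adjusted p = 1.33e-08; adjusted p = 0.275 with an estimated correlation). MYH6 fell by 4.91 on the log2 scale (SE 0.097) and TNNI1 fell by 4.47 (SE 0.16). All 14 proliferation genes were lower, also adjusted over the list alone (camera adjusted p = 6.95e-07; adjusted p = 0.275 with an estimated correlation), with PCNA falling most. All 10 tested members of the HOXA and HOXB list were higher, also adjusted over the list alone (camera adjusted p = 5.77e-06, and 0.275 with an estimated correlation). The filter limits this result too, since members that passed it only through H-EC could hardly be lower there. HOXB6 had 15.7 ± 1.495 TPM in H-EC and 0.711 ± 0.782 in CPC. Of 14 arterial genes, 11 were higher, 2 were lower and 1 did not pass, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.000665; adjusted p = 0.395 with an estimated correlation). DLL4 had 18.4 ± 1.37 TPM in H-EC and 0.121 ± 0.049 in CPC, while CXCR4 was lower, at 4.48 ± 0.175 against 41.8 ± 7.15. Of 15 cardiac transcription factors, 11 were lower and 2 higher, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.00144; adjusted p = 0.293 with an estimated correlation). SMYD1 had 0.419 ± 0.055 TPM in H-EC and 24.8 ± 4.77 in CPC, and ISL1, a factor of cardiac progenitors, had 2.64 ± 0.461 and 25.9 ± 4.32.

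Of 9 venous and lymphatic genes, 6 were higher and 2 lower, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.322 with an estimated correlation). STAB1 had 40.0 ± 4.88 TPM in H-EC and 0.438 ± 0.149 in CPC. Of 11 stress genes, 7 were higher and 1 lower, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.322 with an estimated correlation). JUNB had 4.83 ± 0.106 TPM in H-EC and 0.797 ± 0.011 in CPC. Of 13 hypoxia and glycolysis genes, 8 were lower and 1 higher, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.293 with an estimated correlation). PDK1 had 11.7 ± 1.59 TPM in H-EC and 60.5 ± 3.22 in CPC. Of 6 genes of myeloid cells and leukocytes, another cell type, 4 were higher and 1 lower, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.0348; adjusted p = 0.322 with an estimated correlation). LAPTM5 had 26.4 ± 3.51 TPM in H-EC and 0.300 ± 0.018 in CPC, and CD68 had 28.6 ± 0.799 and 1.03 ± 0.024. In C-EC both stood higher still, with LAPTM5 at 81.6 and 73.8 TPM and CD68 at 44.7 and 46.6 in its libraries. The same list had 4 genes higher and 2 lower in C-EC minus CPC, with no call (camera adjusted p = 0.175, and 0.023 with no filter). CD14, CSF1R, CD33, MPO, LYZ and TYROBP stayed under 1 TPM in every library and were not tested. The myeloid call in H-EC minus CPC ended with a filter of 5 TPM (adjusted p = 0.0742), over a range of 0.000205 to 0.322 in the 18 alternatives. Of 15 regulators of hemogenic endothelium and blood, 8 were higher, 3 were lower and 4 did not pass, with 9 and 3 adjusted over the list alone and no call (camera adjusted p = 0.065; adjusted p = 0.478 with an estimated correlation). This list passed as higher with no filter (0.00165) or a filter of 5 TPM (0.0423), and without H-EC replicate 1 (0.0427). Of 13 endoderm genes, 7 were lower and 1 higher, with no call (camera adjusted p = 0.0672; adjusted p = 0.558 with an estimated correlation), and this list passed as lower with no filter (0.0415) and without CPC replicate 2 (0.00791).

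Of 13 fibroblast and matrix genes, also of another cell type, 8 were higher in H-EC, 2 lower and 3 did not pass, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.0486; adjusted p = 0.478 with an estimated correlation). COL1A2 had 185 ± 25.99 TPM in H-EC and 38.7 ± 10.97 in CPC. This list lost its call without C-EC replicate 1 (adjusted p = 0.0586), C-EC replicate 2 (0.0584) or H-EC replicate 1 (0.0939), with a filter of 5 TPM (0.056), quantile scaling (0.0591) or the compared groups alone (0.0612), and among protein-coding genes alone (0.0595), over a range of 0.0166 to 0.478. In all, 7549 genes were higher and 7713 lower in H-EC than in CPC, of which 1590 and 1317 changed at least 2-fold. Among protein-coding genes alone, 3803 were higher and 3738 lower, of which 1063 and 701 changed at least 2-fold. The 6 genes with the largest increase were ECSCR, PLVAP, GJA4, RP5-837J1.1, CD34 and SOX7, and the 6 with the largest decrease were INSL6, MYH6, CBLN2, TNNI1, TNNT2 and NEBL. The call of RP5-837J1.1 (5.94, SE 1.96, limma adjusted p = 0.0467) ended without H-EC replicate 1 (0.108), H-EC replicate 2 (0.154), CPC replicate 1 (0.14) or CPC replicate 2 (0.136). It also ended with no filter (0.191), no variance trend (0.0536) and a pseudocount of 5 (0.0559).

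The histone marks ask which promoters are open to transcription or under repression in each population. HOX promoters differed between the populations: of 21 HOXA and HOXB promoters, 20 carried H3K4me3 in H-EC, 8 in C-EC and 2 in CPC, while 20, 20 and 21 carried H3K27me3. With lists of equal length the H3K4me3 counts were 13 in H-EC, 2 in C-EC and 2 in CPC. Windows of neighbouring HOX genes overlap, so these promoters are not independent. Of 25 pan-endothelial promoters, 19 carried H3K4me3 in C-EC, 20 in H-EC and 6 in CPC. Of 18 sarcomere promoters, 3 carried it in C-EC, 3 in H-EC and 10 in CPC. These are values of 1 list per population and mark, with no spread between replicates.

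At single genes, CDH5, an endothelial cadherin, carried H3K4me3 in both endothelial populations and not in CPC, and CD34 and TAL1 did so beside H3K27me3 in all 3 populations. ACTN2, a sarcomere protein, carried H3K4me3 in CPC and in neither endothelial population. COL3A1 carried H3K4me3 in H-EC alone of the 3 populations, and no H3K27me3. NKX2-5, GATA4 and GATA2 carried both marks in each population, and TBX5 carried H3K27me3 and no H3K4me3 in each. ISL1 carried H3K4me3 in each population and H3K27me3 in H-EC alone. In the canonical window this was a peak of 7 tags, and further H-EC peaks of up to 38 tags lay near another annotated start site. The canonical start sites of HOPX and RUNX1 carried neither mark in any population, while other annotated start sites of each gene carried both marks in each.

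In C-EC, 10265 of 19391 coding promoters carried H3K4me3 only, 3000 both marks, 1071 H3K27me3 only and 5055 neither. In H-EC the counts were 10165, 3090, 1176 and 4960, and in CPC they were 10947, 1769, 1163 and 5512. The median level in C-EC was 10.8 TPM for promoters with H3K4me3 only, 1.57 TPM with both, 0.133 TPM with H3K27me3 only and 0.063 TPM with neither. With lists of equal length, both marks were on 1474 promoters in C-EC, 1214 in H-EC and 1769 in CPC, so the order reversed and CPC had the most. This cut leaves the CPC lists whole and can only lower the other counts, so the reversed order decides nothing. With a MACS score of at least 100 both marks were on 2188 in C-EC, 2028 in H-EC and 1042 in CPC.

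**Figure D3:**
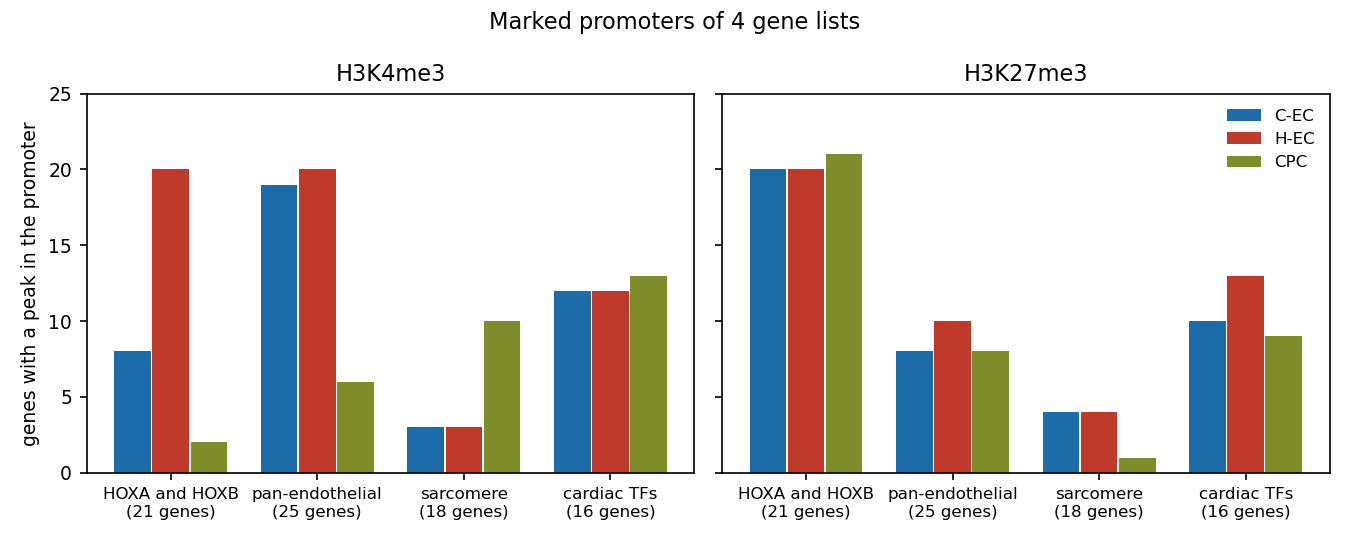
Number of promoters with an H3K4me3 peak (left) or an H3K27me3 peak (right) in 4 gene lists, by population; bars are counts from 1 deposited list per population and mark. H3K4me3 stands on 20 HOXA and HOXB promoters in H-EC, 8 in C-EC and 2 in CPC.

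The lists differed in length: H3K4me3 had 39445 peaks in C-EC, 37880 in H-EC and 18109 in CPC, and H3K27me3 had 30720, 51016 and 15261. Of the CPC H3K4me3 peaks, 96.5% overlapped a C-EC peak (Wilson 95% interval 96.2 to 96.8) and 96.2% an H-EC peak (95.9 to 96.4), while 81.2% of C-EC peaks (80.8 to 81.6) and 80.7% of H-EC peaks (80.3 to 81.1) overlapped a CPC peak. Of the H-EC H3K4me3 peaks, 84.2% overlapped a C-EC peak (83.9 to 84.6), and 82.3% of C-EC peaks an H-EC peak (82.0 to 82.7). Of the C-EC H3K27me3 peaks, 73.4% overlapped an H-EC peak (72.9 to 73.9), and 62.5% of H-EC peaks a C-EC peak (62.0 to 62.9). Of the CPC H3K27me3 peaks, 92.7% overlapped a C-EC peak (92.2 to 93.1) and 90.9% an H-EC peak (90.4 to 91.3), but only 35.5% of C-EC peaks (34.92 to 35.99) and 29.1% of H-EC peaks (28.7 to 29.5) overlapped a CPC peak. With lists of equal length these last shares were 87.76%, 79.15%, 61.08% and 66.65%.

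Genes with H3K4me3 at the promoter in 1 population and not in another formed 6 sets. In all 6 the tested genes were as a set more highly expressed where the mark was present. The filter on low values left 156 of 312 genes for H3K4me3 in H-EC and not in C-EC. It left 471 of 790 for H3K4me3 in H-EC and not in CPC. Genes that passed it through only 1 of the populations compared could hardly be lower in that one, which limits this result. Single genes varied: from 36.7% (H3K4me3 in C-EC and not in H-EC) to 68.2% (in H-EC and not in CPC) were called higher there. Between 6.4% and 10.7% were called lower. The comparisons behind these shares differ, with 40.5% of all tested genes called in H-EC minus C-EC, 57.8% in C-EC minus CPC and 52.6% in H-EC minus CPC. With an estimated correlation none of the 6 sets was called, at a camera adjusted p from 0.0573 to 0.204. The 156 tested genes with H3K4me3 in H-EC and not in C-EC had a median difference of 0.33 on the log2 scale (camera adjusted p = 7.28e-06; adjusted p = 0.204 with an estimated correlation). The 131 with H3K4me3 in CPC and not in C-EC had a median of 0.82 (camera adjusted p = 1.49e-09; adjusted p = 0.0573 with an estimated correlation). The 50 tested genes with H3K27me3 in CPC and not in C-EC had a median of −1.36 in CPC relative to C-EC (camera adjusted p = 1.29e-10; adjusted p = 0.0573 with an estimated correlation). For H3K27me3 in H-EC and not in C-EC the median was −0.13 (camera adjusted p = 0.00623; adjusted p = 0.195 with an estimated correlation), and this call ended among protein-coding genes alone (adjusted p = 0.156). For H3K27me3 in C-EC and not in H-EC the median was −0.02 with no call (camera adjusted p = 0.666), and a call appeared among protein-coding genes alone (adjusted p = 0.0439; adjusted p = 0.375 with an estimated correlation). For H3K27me3 in C-EC and not in CPC the median was −0.09 with no call (camera adjusted p = 0.442), against 0.0251 among protein-coding genes alone (adjusted p = 0.336 with an estimated correlation).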

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

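The fit of protein-coding genes alone, the joining of peaks and the use of any annotated start site were chosen after seeing the data. Of 4441 values of named genes under the alternatives, 4290 kept their direction and side of the threshold and 151 kept their direction but no longer passed. Of 414 values of the 23 called lists under 18 alternatives, 378 kept both and 36 no longer passed. Of 825 values of the 46 lists not called, 63 newly passed, 28 of them with fry and 35, from 11 lists, in other alternatives. Of 144 values of promoter mark sets, 131 kept both, 11 no longer passed and 2 newly passed. Among protein-coding genes alone, 1954 were higher and 3268 lower in H-EC minus C-EC, 4664 and 3694 in C-EC minus CPC, and 3803 and 3738 in H-EC minus CPC; fewer genes were tested, and why the split differs was not tested. In that fit the hypoxia and glycolysis list of C-EC minus CPC newly passed (adjusted p = 0.0446, from 0.131; adjusted p = 0.366 with an estimated correlation), as did the endoderm list and the fibroblast and matrix list of H-EC minus C-EC (0.00763 each; adjusted p = 0.631 with an estimated correlation). At a 2-fold minimum the counts were 845 and 550, 1888 and 1650, and 1590 and 1317, fewer by construction. Of the list tests, 23 of 69 passed with the preset correlation, 0 with an estimated correlation and 51 with fry, which tests another question. Of the 12 mark sets, 10 passed with the preset and 0 with an estimated correlation. Leaving out each library gave 3994 to 5667 genes higher and 3606 (without C-EC replicate 1; 3757 without C-EC replicate 2) to 5421 lower in H-EC minus C-EC, 6334 to 7765 and 6861 to 8681 in C-EC minus CPC, 5927 to 7213 and 5976 to 7282 in H-EC minus CPC, 22 to 28 list calls and 10 to 10 mark sets. Where this left 1 library in a group, that library was assumed to vary like the other groups. With the replicate number as a block, the counts were 5757 and 5454, 7894 and 8703, and 7487 and 7559, with 24 list calls and 10 mark sets. With that block the myeloid list of H-EC minus CPC no longer passed (adjusted p = 0.0516) and the pan-endothelial list and the fibroblast and matrix list of H-EC minus C-EC newly passed (0.0441 each). As a check of pairing, the differences of replicate 1 minus replicate 2 correlated across genes at 0.076 between C-EC and H-EC, 0.004 between C-EC and CPC and −0.004 between H-EC and CPC.

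Peak shares moved as follows, and the cause was not tested. With a MACS score of at least 100, C-EC H3K4me3 peaks were overlapped to 90.44% in H-EC and 82.33% in CPC, and H-EC peaks to 90.04% in C-EC and 81.11% in CPC. For H3K27me3 the shares were 77.19% and 41.55% of C-EC peaks, 80.13% and 39.92% of H-EC peaks, and 96.4% of CPC peaks in C-EC and 93.95% in H-EC. In the same order, with CPC H3K4me3 peaks in C-EC and H-EC added, lists of equal length gave 92.87%, 97%, 92.46%, 96.8%, 79.31% and 79.7% for H3K4me3 and 72.47%, 61.08%, 88.91%, 66.65%, 87.76% and 79.15% for H3K27me3. Peaks joined within 1000 bp gave 90.64%, 81.72%, 91.27%, 82.13%, 97.13% and 96.91%, then 75.51%, 46.58%, 54.65%, 33.53%, 91.53% and 90.24%. An overlap of 50% of the peak gave 74.32%, 80.32%, 76.53%, 79.97%, 78.73% and 78.27%, then 58.58%, 27.52%, 56.34%, 24.14%, 89.63% and 84.71%. Promoters with both marks numbered 1474 in C-EC and 1214 in H-EC with lists of equal length, below the 1769 in CPC, and 2028 in H-EC and 1042 in CPC with a score of at least 100. The cut to equal length leaves the CPC lists whole and can only lower the other counts. The score rests on tags, of which the CPC H3K27me3 list had the fewest, so neither cut decides the order. The RNA depth is unknown, so what it limits was not assessed.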

Other observations

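The 4 gene groups of the next paragraph, the naming of COL5A1, the counts of promoters with H3K27me3 in both or neither population and of losses with lists of equal length, the H-EC list at equal covered bases, the promoters marked in both H-EC and CPC, and the tests of a fibroblast-like share and of a share that varies between CPC libraries, were chosen only after the result was seen.

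Genes of plasma lipoproteins and coagulation, which liver and yolk sac endoderm make, were higher in H-EC than in C-EC for 9 of 14 members, with none lower; 5 of the 14 (AFP, APOA1, APOA2, APOB and TTR) are also in the endoderm list. Camera p values are not given for these groups, since the members were chosen after the values were seen. APOA2 had 109 ± 6.65 TPM in H-EC and 5.16 ± 0.735 in C-EC (SD, n = 2), and FGB, a fibrinogen chain, had 14.6 ± 0.548 and 0.524 ± 0.175. FGA, FGB and FGG passed the filter only through H-EC, so for these a higher level there was largely set by the filter. All 4 tested GIMAP genes, small GTPases of blood cells, were higher than in CPC in C-EC and in H-EC. GIMAP5 had 47.0 ± 4.82, 47.2 ± 2.47 and 0.570 ± 0.104 TPM in C-EC, H-EC and CPC. Each of the 4 had a CPC mean under 1 TPM and passed the filter only through the endothelial libraries. A higher level than in CPC was therefore largely set by the filter. Of 16 imprinted genes, 5 were higher and 3 lower in H-EC than in C-EC, with a mean of 0.44 and a median of −0.13. In this comparison 40.5% of all tested genes were called, so these counts do not set the imprinted genes apart. H19 had 1761 ± 454 TPM in H-EC and 79.9 ± 0.065 in C-EC, and IGF2 had 341 ± 84.5 and 45.6 ± 7.81. Of 20 axon guidance genes, 8 were lower and 5 higher in H-EC, with NRP2 at 255 ± 20.0 TPM in H-EC and 1080 ± 38.1 in C-EC.

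The H3K4me3 list of CPC was shorter and wider than that of C-EC, which held 2.18 times as many peaks. More marked promoters in C-EC do not account for it, since the ratio of marked coding promoters was 1.043. After peaks within 1000 bp were joined in every list the ratio of peak counts was 1.2, so splitting of wide regions into several peaks may account for most of the gap; MACS used a fragment size of 128 in the CPC list and 41 in the C-EC list. Peaks away from any annotated promoter were 3.43 times as many in C-EC, so such peaks may add to it. The CPC input had 5324749 tags against 21683346 for C-EC, and its part stays open.

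H3K27me3 lay on 1403 promoters in H-EC that did not carry it in CPC. With lists of equal length 37% of them (519) kept the difference, and with an H-EC list that covers as many bases as the CPC list 14.7% (206). These tests shorten only the H-EC list, whose peaks are narrower (median 177 bp against 488 bp), and can only lower the count, but promoters marked in both kept the mark in H-EC at 92.8% and 83.1%, so weaker peaks of the longer list may account for part of the difference. The genes of all these promoters had a median expression difference of −0.169 in H-EC relative to CPC, called by camera (adjusted p = 0.018), which is consistent with lower expression where the mark is present, though the size is small, and with an estimated correlation the adjusted p = 0.29. A difference in Polycomb repression between the populations stays open and untested, since the lists used here are not split by replicate.

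COL3A1 and LUM were among 79 genes at least 4-fold higher in H-EC than in C-EC. The values go against complete loss of promoter H3K27me3 as their common cause. Of the 53 coding genes among them 27 carried it in neither population, 26 carried it in both and 0% lost it (upper Wilson 95% limit 6.8%). Of all tested coding genes 1.8% lost it, and with lists of equal length 1 gene among the 53 did. A weaker mark at the 26 promoters stays open, since peaks were scored only as present or absent. The H-EC list was also longer (51016 peaks against 30720 in C-EC), which makes a loss harder to call. A fibroblast-like share of cells stays open: 7 of 13 fibroblast and matrix genes were higher and 2, PDGFRA and COL5A1, were lower, but at their level above 20 TPM in C-EC a fall in the other cells would hide an added share. A share of cells that also varies between the CPC libraries stays open too. The median difference between CPC replicates over the 79 genes was 0.091 (0.1 for the coding genes). It lay above 99.99% of 10000 lists matched on expression, which goes with such a share. The 79 include COL3A1 and LUM, however, whose gap between CPC replicates had already been seen. Its size fell short of the bound set for this cause. It also lay under the bound of 0.1 set against it, by less than its standard error of 0.038 from resampling genes. A margin beyond that error was asked for only after the value was seen. By the rule as first written, the value counted against this cause. The value also rests on 2 single libraries and on genes that are not independent, so it does not decide. The activin A and BMP4 doses, which the design varies, stay open and untested. BMP pathway targets had 2 genes higher and 2 lower in H-EC than in C-EC, with 9 that did not pass and no call (camera adjusted p = 0.91). NODAL and activin targets had 2 higher, 2 lower and 3 that did not pass, with no call either (0.662). These lists describe day 5 and do not test the doses themselves. H3K4me3 was gained in H-EC at 9 of the 53 (17%), against 1.2% of all tested coding genes. The 53 were chosen for higher expression in H-EC, so this share favours no cause.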
